A study of Homo sapiens with 18 samples.

How the data were processed

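RNA was measured in PEO1 cells, a human high-grade serous ovarian cancer line, transfected with a control siRNA (siControl) or an siRNA against p53 (sip53) and treated with 10 nM estradiol (E2) for 0, 2 or 8 h. Cells were kept in hormone-depleted medium before E2, and the 0 h samples were untreated. Each of the 6 groups held 3 samples, 18 in all. The libraries were made with the QuantSeq 3' mRNA-Seq FWD kit, which reads from the 3' end of transcripts, so a count reflects transcript ends and not transcript length. The deposited table holds RSEM expected counts per gene, made by the authors. Their processing notes name RSEM 1.3.3, Bowtie2, cutadapt, MultiQC and genome build hg19. The annotation behind those counts is not given in the sources used here. The deposited expected counts were already whole numbers, so rounding them before testing moved none.

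The table had 57736 rows, each identified by a set of Ensembl transcripts. They were named through GENCODE v29, an annotation of build GRCh38, and current gene symbols. A single gene named 52769 rows, a majority of transcripts named 219, no gene had a majority in 106, and 4642 had no transcript in that annotation. Rows without a name held 0.599% of all counts. Because the counts were made on another build, genes are identified by transcript and symbol, and every coordinate printed is on GRCh38. No row held a mitochondrially encoded gene.

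Total counts ran from 7542457 to 11307199 per sample. The biological coefficient of variation over all genes was 15.2% (common dispersion 0.0232), so the spread between samples and not counting error set the precision for most genes named. The pairs of samples within a group differed by more than counting noise, with a chi-square per degree of freedom of 4.04 to 22.92 over genes with at least 20 counts, so no library was a copy of another in its group. The labels do not say that the 3 samples of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

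Tests were run with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr (minimum count 10), which left 15318 genes, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 18 samples with 1 coefficient per group. The 11 contrasts were sip53 against siControl at each of the 3 times, E2 at 2 h and at 8 h against 0 h in each arm, 8 h against 2 h in each arm, and the difference between the arms in the E2 response at 2 h and at 8 h. A gene was called changed when its Benjamini-Hochberg adjusted p was under 0.05 within a contrast. Log2 fold changes are given with their standard error (SE), and levels as mean TMM-normalised CPM ± SD with n = 3. The 3 contrasts at different times within an arm share libraries, so their results are not independent of each other.

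The samples, contrasts, tests, gene lists, rule for named genes and alternatives were chosen before the data were examined. The rule included ESR1 and the genes with the largest fold change in each direction among those called. Those had an average log2 CPM of at least 3 and no overlap between the 2 groups, so all 3 samples of one group lay above all 3 of the other. It took 10 per direction for the main contrasts and 5 for the others. For each gene list it took up to 4 called members per direction with the smallest adjusted p. A gene named in one contrast may be given in any other. GREB1, MDM2 and CCND1 are also given, although the rule does not name them.

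The 25 gene lists covered estrogen-induced genes, estrogen-repressed genes, estrogen receptors and cofactors, p53-activated targets, p53 family and regulators, DNA replication, mitosis, homologous recombination, ribosome biogenesis, cytosolic ribosomal proteins, cholesterol synthesis and uptake, fatty acid synthesis, unfolded protein response chaperones, the ATF4 stress response, interferon response, NF-kB and inflammatory genes, immediate-early genes, mesenchymal and matrix genes, epithelial and ovarian carcinoma markers, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, and fibroblast, leukocyte and endothelial markers. Lists with at least 3 measured members were tested, which was 22 of them. The test was camera from limma 3.58.1 with a preset correlation of 0.01 between genes, repeated with an estimated correlation, each adjusted by Benjamini-Hochberg over the 22 lists within a contrast. For the estrogen and p53 lists fry was also run, which tests whether a list's genes move, on balance, one way. The mitochondrially encoded list had 0 measured members and the leukocyte and endothelial lists had 2 each, so these were not tested. Results of the p53 family and regulators list, and of some single genes, are not reported here.

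The size of the E2 response in the 2 arms was compared over genes chosen by an adjusted p under 0.05 for the E2 effect averaged over both arms, a choice that favours neither arm. The difference between arms was signed by the direction of the average effect and tested with fry. Because fry's p is not exact with 3 samples per group, it was used only to call a difference at 0.05, beside random regroupings of the samples.

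On simulated data with known 1.5-fold, 2-fold and 4-fold changes in 67, 67 and 66 genes, the same test recovered 46.3% of 2-fold changes and 84.8% of 4-fold changes for sip53 against siControl at 0 h, with 5 false calls among 116. For the difference between arms at 8 h it recovered 7.5% of 1.5-fold, 34.3% of 2-fold and 74.2% of 4-fold changes, with 4 false calls among 81. The adjusted threshold depends on how many genes change, so these shares hold for data with that many changed genes.

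The alternatives tried were RLE and upper-quartile scaling, no filter, a filter at 1 CPM in 3 samples, a 2-fold threshold, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit to the contrast's groups only, and each library left out in turn. Replicate numbers were not treated as pairs. Residual correlations between samples that share a number ran from -0.364 to 0.437, with 15 of 45 pairs above 0.1, and 6 of 18 samples correlated best with their own number. For questions raised in the closing section, the 3' UTRs of 12410 genes were searched for 7-base words associated with lower expression in sip53, and a trend with transcript length and GC content was estimated and removed from each library. Medians with that trend removed come from the edgeR fit. The camera tests beside them ran on log2 CPM values, not on the edgeR counts, and may remove the trend once more. A call gained or lost in this altered camera test is therefore not credited to the trend alone. Reads were not realigned, and no protein data were used here.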

Results

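Gene expression was measured in PEO1 ovarian cancer cells, a line that carries mutant p53 according to the series title. There were 6 groups of 3 samples each, formed by 2 siRNAs (siControl and sip53) and 3 times with 10 nM estradiol (0, 2 and 8 h). The series title raises the question of whether p53 in these cells restrains the activity of the estrogen receptor ESR1. Total counts per sample were 7542457 to 10132570 in the siControl samples and 9225939 to 11307199 in the sip53 samples. The 100 most abundant genes took 21.12% to 22.87% of the counts in every sample. In a principal component analysis the first component (24.1% of the variance) held all 9 siControl samples at -10.6 or below and all sip53 samples at -3.1 or above. Library siControl 0 h replicate 2 stood apart. It lay at -41.7 on the second component (10.8% of the variance), had the lowest depth of all samples, and had the largest distance from the other replicates of its group (root mean square 0.39). It enters every comparison with siControl at 0 h.

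ESR1, the receptor that binds E2 (ENSG00000091831, chromosome 6, 151656691 to 152129619 on GRCh38), was higher after the knockdown. Its level was 67.2 ± 10.5, 68.9 ± 12.1 and 62.3 ± 2.45 CPM in siControl at 0, 2 and 8 h, and 95.4 ± 2.48, 89.3 ± 3.87 and 84.3 ± 4.68 CPM in sip53 (n = 3 each). The log2 fold change was 0.51 ± 0.12 at 0 h (adjusted p = 0.0114), 0.37 ± 0.12 at 2 h (0.0401) and 0.44 ± 0.12 at 8 h (0.0237). At 0 h the call was lost without sip53 0 h replicate 3 (adjusted p = 0.0589) and in a fit to these 2 groups alone (adjusted p = 0.0754). At 2 h it was lost without siControl replicate 1 (0.154), siControl replicate 2 (0.181), or sip53 replicate 1 (0.0795), 2 (0.101) or 3 (0.16). At 8 h it was lost without siControl replicate 1 (0.0843), siControl replicate 2 (0.0922), or sip53 replicate 1 (0.0887) or 2 (0.0583). E2 did not move ESR1 past the threshold in either arm, with 8 h log2 values of -0.11 ± 0.12 in siControl and -0.18 ± 0.12 in sip53.

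**Figure D1:**
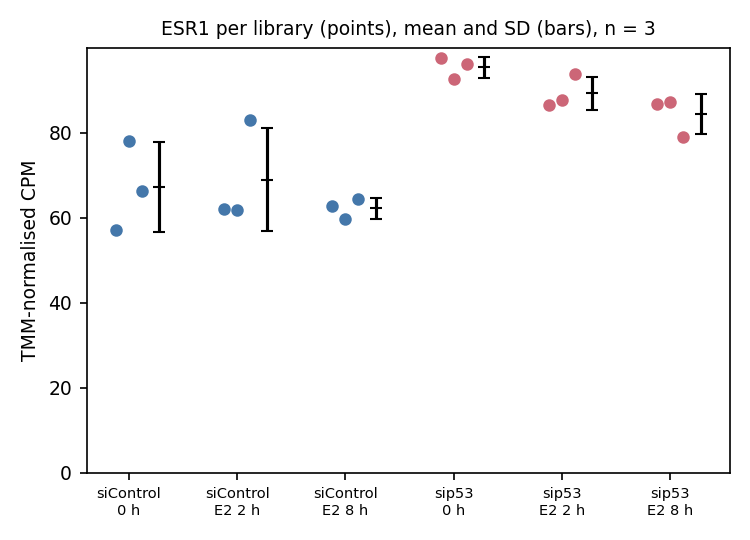
ESR1 in TMM-normalised CPM for each library (points), with mean and SD (bars, n = 3) for the 6 groups. Every sip53 library held more ESR1 than every siControl library at the same time.

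The first comparison asked what the p53 siRNA did to the transcriptome without E2. At 0 h, 610 genes were higher and 787 lower in sip53 than in siControl, out of 15318 tested (3886 at an unadjusted p under 0.05). The knockdown used a single siRNA reagent, so effects of p53 and of the reagent are not separated. Genes that were higher included TSPAN2, a tetraspanin (log2 1.62 ± 0.20, 10.5 ± 1.81 CPM against 31.9 ± 4.7, n = 3 each), and TNS3, a tensin of focal adhesions (1.22 ± 0.15). Other large rises were ADAMTS15, a matrix protease (1.08 ± 0.22), FNIP2, a partner of folliculin (1.08 ± 0.24), SLC17A5, the lysosomal sialic acid exporter (1.05 ± 0.19), and CITED2, a transcriptional coregulator (0.98 ± 0.16). The thiamine transporter SLC19A2 (1.15 ± 0.34) and the CREB coactivator CRTC2 (1.11 ± 0.31) also rose, with calls kept in 2 and 3 of the 6 fits that left out 1 library. The kinase WNK4 fell by 2.13 on the log2 scale. An unnamed gene, ENSG00000243107, rose by 2.7 ± 0.45. SLC19A2, CRTC2, WNK4 and ENSG00000243107 were also among the largest changes with E2 in siControl, at 2 h or 8 h and in the same direction. Both comparisons use the same siControl 0 h samples. An unusual level in those samples would give both changes, so they are not separate findings.

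Among the 33 measured p53-activated targets, 2 were higher, 4 were lower and the rest were not called at 0 h (3 higher and 7 lower adjusted over the list alone), with a median log2 fold change of -0.18. RPS27L, a ribosomal protein paralog induced by p53, fell from 97.1 ± 7.36 to 27.6 ± 14.3 CPM (log2 -1.81 ± 0.24, adjusted p = 0.000162). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell from 22.3 ± 3.78 to 13.6 ± 1.29 CPM (-0.71 ± 0.17, adjusted p = 0.0127), and SESN2, a stress-induced regulator of mTORC1, was lower (-0.48 ± 0.12, 0.0149). These 2 calls were kept in 4 of the 6 fits that left out 1 library. The death receptor TNFRSF10A was also lower (-0.44 ± 0.10). DRAM1, an autophagy gene (0.53 ± 0.10), and CCNG1, a cyclin G (0.89 ± 0.19), went the other way. MDM2, the ubiquitin ligase that p53 induces, did not differ past the threshold (-0.02 ± 0.14). With camera, which compares a list with all other genes, the list missed the threshold at 0 h (camera adjusted p = 0.0794). With fry, which does not compare it with other genes and was not adjusted over lists, it was called lower at 0.05 at 0, 2 and 8 h.

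Cholesterol genes moved together. Of 24 measured genes of cholesterol synthesis and uptake, 12 were higher and 0 lower in sip53 at 0 h (19 higher and 0 lower adjusted over the list alone). The median log2 fold change was 0.43, and the list was called with the preset correlation (camera adjusted p = 1.59e-14) and with an estimated one (adjusted p = 0.0151 with an estimated correlation). HMGCS1, which makes HMG-CoA for the pathway, rose from 87.6 ± 13.9 to 159 ± 18.2 CPM (log2 0.86 ± 0.12, adjusted p = 0.000183). FDFT1, which makes squalene, rose by 0.67 ± 0.11, DHCR7, the last enzyme of synthesis, by 0.59 ± 0.10 and EBP, a sterol isomerase, by 0.50 ± 0.08. The neighbouring list of fatty acid synthesis was split. SCD (0.70 ± 0.10), ELOVL5 (0.62 ± 0.11) and FASN (0.35 ± 0.08) were the 3 higher members of 11 (5 higher and 1 lower adjusted over the list alone), while ACLY, which supplies cytosolic acetyl-CoA, fell from 230 ± 33.7 to 114 ± 5.33 CPM (-1.01 ± 0.11, adjusted p = 9.98e-06). That list was not called (camera adjusted p = 0.0686).

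Ribosomal proteins and oxidative phosphorylation genes were mostly shifted upward at 0 h. Of 40 cytosolic ribosomal proteins 11 were higher and 0 lower (29 and 0 adjusted over the list alone), with RPL24 at 0.45 ± 0.12 and RPS2 at 0.39 ± 0.11, and a median of 0.32. Of 32 nuclear-encoded oxidative phosphorylation genes 16 were higher and 0 lower (22 and 0 adjusted over the list alone), with UQCRC1 at 0.42 ± 0.10 and NDUFB5 at 0.50 ± 0.12, and a median of 0.36. Both were called by camera with the preset correlation (adjusted p = 4.81e-12 and 1.83e-11) but not with an estimated one (adjusted p = 0.233 and 0.209 with an estimated correlation). Epithelial and ovarian carcinoma markers had 4 of 21 members higher and 0 lower (9 and 0 adjusted over the list alone), among them the keratin KRT19 (0.47 ± 0.09). Their median was 0.23, and the list was called with the preset correlation only (0.00124, and adjusted p = 0.209 with an estimated correlation). With each library's trend with transcript length and GC content removed, the median was 0.134. The altered camera test used there did not call the list (adjusted p = 0.291). ATF4 stress genes had 1 member higher and 3 lower of 20 (1 and 5 adjusted over the list alone), with SLC7A11, the cystine transporter, at -0.71 ± 0.09 and ALDH1L2, a mitochondrial folate enzyme, at -1.13 ± 0.20. Their median was -0.08 (camera adjusted p = 0.0254, adjusted p = 0.233 with an estimated correlation), and -0.171 with the length and GC trend removed (adjusted p = 0.00152, and adjusted p = 0.0889 with an estimated correlation).

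The estrogen-induced list was not called as shifted by the knockdown without E2 (42 measured, 1 higher, 4 lower, 3 and 5 adjusted over the list alone, median 0.13, camera adjusted p = 0.774). With the length and GC trend removed the median of this list was 0.045. Its called members included some of the best known estrogen targets, and they were lower. AREG, an EGF receptor ligand, stood at 61.1 ± 5.92 CPM in siControl and 32.6 ± 4.63 in sip53 (log2 -0.90 ± 0.17). SLC26A2, a sulfate transporter, was lower by log2 -0.66 ± 0.12, STC2, a secreted glycoprotein, by -0.48 ± 0.08 and XBP1, a transcription factor of the secretory pathway, by -0.36 ± 0.09 (call kept in 2 of the 6 fits that left out 1 library). FHL2, a LIM domain coregulator, was higher (0.31 ± 0.10, call kept in 2 of the 6). Of 10 estrogen-repressed genes 2 were higher and 0 lower, ERBB3 (0.47 ± 0.10) and CCNG2 (0.73 ± 0.17), with a median of 0.20 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0686, called higher by fry). Of 18 receptors and cofactors 3 were higher and 0 lower (3 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.13), including ESR1 and the AP-2 factor TFAP2C (0.36 ± 0.09). With the length and GC trend removed the altered camera test called that list with the preset correlation at 0 h and 2 h (medians 0.162 and 0.081, adjusted p = 0.00285 and 0.0118, and adjusted p = 0.0495 and 0.0944 with an estimated correlation). That test also called fatty acid synthesis genes, with the preset correlation only (medians 0.167 and 0.291, adjusted p = 0.0345 and 0.0366, and adjusted p = 0.0889 and 0.186 with an estimated correlation).

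Cell-cycle and repair lists held few calls at 0 h. Of 40 DNA replication genes 1 was higher and 1 lower, the polymerase subunit POLA1 (-0.63 ± 0.18), of 33 mitosis genes 1 was higher and 1 lower, the kinetochore motor CENPE (-0.64 ± 0.13), and of 21 homologous recombination genes 0 were higher and 2 lower, including BRCA1 (-0.31 ± 0.09). Their medians were 0.10, -0.04 and -0.21, and camera called none of these 3 lists (adjusted p = 0.13, 0.468 and 0.0699). Adjusted over the list alone the counts were 0 and 0, 1 and 1, and 0 and 2.

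Several of the largest falls came from pseudogenes or members of multi-copy families, whose reads map to more than 1 place, and are uncertain as measures of a single gene. They were NPIPB3, NPIPA8, NPIPB11, PDXDC2P, HNRNPA3P6, EIF1AXP1, TCEA1P2 and CTAGE8, the last of which had 0 counts in the 3 sip53 samples at 0 h. The total of 1397 changed genes moved with the libraries used. Left out in turn, siControl 0 h replicate 1 gave 2043 (1052 of them higher), replicate 2 gave 732 and replicate 3 gave 610. Without sip53 0 h replicate 1 the lower genes numbered 1199. Leaving out sip53 0 h replicate 2 gave 511 changed genes and replicate 3 gave 289, and a fit to these 2 groups alone gave 284. Of the 87 named calls at 0 h, 34 were kept in every fit that left out 1 library.

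The knockdown was compared again at 2 h and 8 h of E2, which asked whether its effects were present with the hormone. Of the genes called, 159 were higher in sip53 at all 3 times (0.76 expected if the calls were independent) and 416 were lower at all 3 times (3.77 expected), with 0 called in opposite directions by edgeR. The 3 comparisons use different libraries but come from 1 fit that shares each gene's estimate of spread. Their calls are therefore not fully independent, and the expected numbers are a rough guide. At 2 h 677 genes were higher and 1194 lower, and at 8 h 431 were higher and 941 lower. With each library's trend with transcript length and GC content removed, edgeR called 732 higher and 892 lower at 2 h. At 8 h it then called 540 higher and 664 lower. With upper-quartile scaling the 8 h counts were 617 higher and 838 lower, so the share of higher genes moved from 31.4% to 42.4%. Left out in turn, siControl 2 h replicate 2 gave 862 changed genes at 2 h, replicate 3 gave 1190, sip53 2 h replicate 2 gave 1076 and replicate 3 gave 821. At 8 h siControl replicate 1 gave 505, replicate 2 gave 703, sip53 replicate 1 gave 789 and replicate 3 gave 399.

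TSPAN2 stayed higher with E2 (1.5 ± 0.20 at 2 h and 1.39 ± 0.19 at 8 h, in log2). MED18, a subunit of Mediator, was higher at 2 h (1.11 ± 0.23). The carboxypeptidase CPA4 (1.27 ± 0.14), the keratin KRT15 (1.28 ± 0.25) and the growth factor IGF1 (1.21 ± 0.25) were higher at 8 h. KRT19 was higher at both (0.59 ± 0.09 and 0.70 ± 0.09). Epithelial markers had 7 higher and 1 lower of 21 at 2 h and 4 higher and 2 lower at 8 h (8 and 2, and 5 and 2, adjusted over the list alone). Their medians were 0.08 and 0.21 (camera adjusted p = 0.0293 and 0.00339, adjusted p = 0.272 and 0.204 with an estimated correlation). With the length and GC trend removed the medians were 0.073 and 0.144, and the altered camera test called neither (adjusted p = 0.779 and 0.735). Its direction at 2 h was down, although that median was positive. Among the lower genes ESM1, an endothelial proteoglycan, stood at -1.13 ± 0.16, -1.30 ± 0.16 and -1.22 ± 0.18 at 0, 2 and 8 h.

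With E2 for 2 h 1 of 33 p53 targets was higher and 8 lower in sip53 (2 and 8 adjusted over the list alone, median -0.16), and at 8 h 2 were higher and 10 lower (3 and 15 adjusted over the list alone, median -0.29). The list was called at 8 h with the preset correlation (camera adjusted p = 0.000175) and with an estimated one (adjusted p = 0.0191 with an estimated correlation). At 2 h it was called only with the preset correlation (0.0103, and adjusted p = 0.116 with an estimated correlation). With the length and GC trend removed the 8 h median of -0.286 became -0.292. The altered camera test called the list at 8 h with the preset correlation (0.00299) but not with an estimated one (adjusted p = 0.101). Without sip53 8 h replicate 3 the 8 h median was -0.177. RPS27L stood at -2.30 ± 0.25 and -2.21 ± 0.25, and CDKN1A at -1.22 ± 0.17 and -0.98 ± 0.17. ZMAT3, an RNA-binding growth suppressor (-0.91 ± 0.16), and XPC, a DNA damage sensor (-0.54 ± 0.11), were lower at 2 h. SESN2 (-0.77 ± 0.11) and GADD45A, a stress-induced growth arrest gene (-0.77 ± 0.16), were lower at 8 h. DRAM1 stayed higher (0.43 ± 0.10 and 0.44 ± 0.10).

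Cholesterol genes stayed higher. Of 24 measured, 14 were higher at 2 h and 13 at 8 h and 0 were lower (16 and 17 higher adjusted over the list alone), with medians of 0.38 and 0.42. HMGCS1 stood at 0.65 ± 0.12 and 0.92 ± 0.12, DHCR7 at 0.53 ± 0.10 and 0.59 ± 0.10, ACAT2 at 0.62 ± 0.12 at 2 h and SQLE, squalene epoxidase, at 0.53 ± 0.08 at 8 h. Camera called the list at both times (adjusted p = 2.4e-10 and 1.16e-14). With an estimated correlation it was called at 8 h (adjusted p = 0.0168 with an estimated correlation) and not at 2 h (adjusted p = 0.0642 with an estimated correlation). Fatty acid genes again went both ways, with SCD at 0.55 ± 0.10 at both times and ACLY at -1.07 ± 0.11 and -0.81 ± 0.11. Of 11 measured, 4 were higher and 1 lower at 2 h and 2 higher and 1 lower at 8 h (6 and 2, and 4 and 1, adjusted over the list alone). That list was not called (camera adjusted p = 0.174 and 0.249).

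Of 20 ATF4 stress genes 1 was higher and 6 were lower in sip53 at 8 h (1 and 9 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.35e-06, adjusted p = 0.0524 with an estimated correlation). The higher member was SLC7A5, an amino acid transporter (0.32 ± 0.10, adjusted p = 0.0363). With each library's trend with transcript length and GC content removed the median was -0.355. The altered camera test called the list with an estimated correlation too (adjusted p = 0.0199). SLC7A11 stood at 114 ± 6.46 CPM in sip53 and 241 ± 11 in siControl (log2 -1.08 ± 0.09, adjusted p = 1.45e-07). ALDH1L2 was lower by -1.42 ± 0.20 and CHAC1, which degrades glutathione, by -0.61 ± 0.14. At 2 h the list held 1 higher and 2 lower members and was not called (1 and 2 adjusted over the list alone, median -0.045, camera adjusted p = 0.235). The altered camera test called it at 2 h with the preset correlation only (0.0177, and adjusted p = 0.205 with an estimated correlation). Unfolded protein response chaperones held 0 higher and 3 lower of 16 at each time with E2 (1 and 5 at 2 h and 0 and 3 at 8 h adjusted over the list alone), among them the ER chaperone HSP90B1 (-0.85 ± 0.15 and -0.64 ± 0.15). They were called at 2 h only with the preset correlation (camera adjusted p = 0.0293, adjusted p = 0.295 with an estimated correlation).

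Of 33 mitosis genes 8 were lower and 1 higher in sip53 at 2 h, and 5 lower and 0 higher at 8 h (10 and 2, and 8 and 1, adjusted over the list alone). CENPE stood at -0.88 ± 0.13 and -0.78 ± 0.13 and ASPM, a spindle pole gene, at -0.99 ± 0.20 and -0.86 ± 0.20. The list medians were -0.10 and -0.17 (camera adjusted p = 0.0293 and 0.00175, adjusted p = 0.608 and 0.432 with an estimated correlation). With the length and GC trend removed the medians were -0.094 and -0.135, and the altered camera test called neither (adjusted p = 0.536 and 0.0937). Of 21 homologous recombination genes 6 were lower and 1 higher at 2 h and 4 lower and 0 higher at 8 h, among them BRCA2 (-1.01 ± 0.21 and -0.87 ± 0.21), with 7 and 2, and 5 and 0, adjusted over the list alone. That list was not called (camera adjusted p = 0.11 and 0.0761). Ribosomal proteins had 20 of 40 higher at 2 h and 0 at 8 h, and oxidative phosphorylation genes 14 and 2 of 32, with 0 lower in either list (27 and 0, and 17 and 10, higher adjusted over the list alone). Their medians at 8 h were 0.21 and 0.27, and neither was called at 2 h or 8 h with an estimated correlation (adjusted p = 0.272 and 0.466 for ribosomal proteins and 0.272 and 0.371 for oxidative phosphorylation with an estimated correlation, against 1.13e-13, 8.56e-06, 4.91e-08 and 4.34e-07 with the preset one). With the length and GC trend removed the 8 h median of ribosomal proteins was 0.156, and the altered camera test did not call them (adjusted p = 0.0514).

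The estrogen-induced list was again not called as shifted between the arms with E2 (median 0.17 at 2 h and 0.23 at 8 h, camera adjusted p = 0.665 and 0.316). Its median was positive at all 3 times, so a missed threshold does not show that no shift exists. With the length and GC trend removed the medians were 0.115 at 2 h and 0.138 at 8 h. The altered camera test called neither (adjusted p = 0.833 and 0.453). At 2 h 2 members were higher and 4 lower, and at 8 h 4 were higher and 4 lower (2 and 4, and 5 and 5, adjusted over the list alone). CISH, a feedback inhibitor of cytokine signalling, was higher in sip53 at 8 h (0.82 ± 0.18, call kept in 4 of the 6 fits that left out 1 library), and so was the corepressor ZNF703 (0.83 ± 0.20, kept in 3). AREG stayed lower (-1.31 ± 0.17 and -1.29 ± 0.17), as did SLC26A2 (-0.84 ± 0.12 and -0.88 ± 0.12) and XBP1 (-0.54 ± 0.09 and -0.44 ± 0.09). TFAP2C was higher at both times (0.73 ± 0.09 and 0.41 ± 0.09). TXNIP, an inhibitor of glucose uptake on the estrogen-repressed list, was lower at 8 h (-1.24 ± 0.16).

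**Figure D2:**
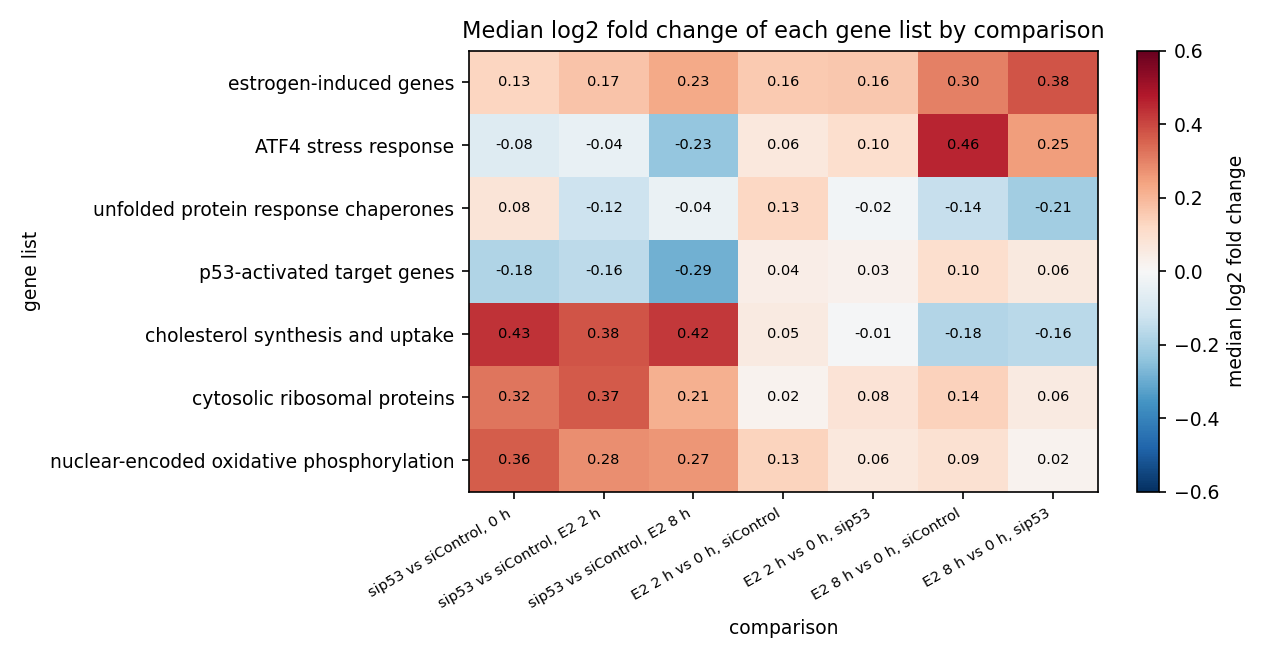
Median log2 fold change of 7 gene lists (vertical axis) in 7 comparisons (horizontal axis), with the value printed in each cell and colour from -0.6 to 0.6. Cholesterol genes stood at 0.38 to 0.43 in the 3 comparisons of sip53 with siControl, and ATF4 stress genes at 0.455 and 0.25 after 8 h of E2 in siControl and sip53.

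The E2 response was first measured in siControl, where the question was which genes estrogen moves in these cells. No vehicle samples at 2 h or 8 h were among those analysed, so the effect of E2 and that of the time itself are not separated. After 2 h 35 genes were higher and 0 lower, with 1748 genes at an unadjusted p under 0.05 (edgeR). The counts lower were 29 with DESeq2, 1 with limma-voom and 32 without siControl 0 h replicate 1. CISH led, from 2.11 ± 0.522 to 19.3 ± 3.11 CPM (log2 3.16 ± 0.22, adjusted p = 1.42e-08). SLC22A5, the carnitine transporter (1.59 ± 0.18), LONRF2, a ubiquitin ligase (1.42 ± 0.18), and SLC19A2 (1.70 ± 0.33, call kept in 3 of the 6 fits that left out 1 library) rose, as did the unannotated transcript ENST00000541740 (2.23 ± 0.26). The rise of SLC19A2 rests on the same siControl 0 h samples as its knockdown change. TFAP2C (0.72 ± 0.09) and the matricellular gene CCN1 (0.98 ± 0.17) also rose. Of 42 estrogen-induced genes 2 rose, CISH and KLF4 (0.89 ± 0.18, call kept in 1 of the 6), and 0 fell (6 and 0 adjusted over the list alone). The list had a median of 0.16 and was called with both correlations (camera adjusted p = 2.61e-08, adjusted p = 0.000414 with an estimated correlation). The median was 0.239 without 2 h replicate 1 and 0.238 without 0 h replicate 2. Unfolded protein response chaperones had a median of 0.13 with 0 members called (4 higher adjusted over the list alone), and were called with the preset correlation only (6.37e-05, and adjusted p = 0.203 with an estimated correlation). The total of 35 became 144 without siControl 0 h replicate 1, 19 without 0 h replicate 2, 18 without 2 h replicate 2, 17 without 2 h replicate 3, 13 in a fit to these 2 groups, and 130 with DESeq2.

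After 8 h of E2 in siControl 273 genes were higher and 126 lower. CISH stood at 12.9 ± 2.13 CPM (2.58 ± 0.23), and RASGRP1, a Ras activator, rose from 15.2 ± 1.87 to 49.8 ± 6.56 CPM (1.71 ± 0.13, adjusted p = 7.7e-08). LONRF2 (1.65 ± 0.18), the organic cation transporter SLC22A3 (1.60 ± 0.19), CRTC2 (1.76 ± 0.30) and ST6GALNAC2, a sialyltransferase (1.55 ± 0.26), also rose. For CRTC2 this rise and the knockdown change at 0 h rest on the same siControl 0 h samples. Of 42 estrogen-induced genes 8 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.82e-11, adjusted p = 0.00012 with an estimated correlation). STC2 went from 484 ± 21.5 to 967 ± 69.7 CPM (1.00 ± 0.08), XBP1 from 77.1 ± 1.85 to 128 ± 10 (0.73 ± 0.09) and KLF4 from 19.5 ± 7.36 to 48.1 ± 3.32 (1.29 ± 0.18). MYC rose by 1.19 ± 0.23. GREB1, a standard estrogen target, was near the floor (1.35 ± 0.972 CPM at 0 h and 3.01 ± 1.51 at 8 h) and was not called. Of 10 estrogen-repressed genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), against the direction of the list's name. They were TXNIP (1.23 ± 0.17), HES1, a Notch target (1.05 ± 0.18), and KLF9 (0.73 ± 0.18, call kept in 2 of the 6). The median was 0.15 (camera adjusted p = 0.000304, adjusted p = 0.0388 with an estimated correlation).

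Among the 22 tested lists the ATF4 stress list had the largest median after 8 h in siControl. There 8 of 20 members rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.455 (camera adjusted p = 6.84e-29, adjusted p = 0.000244 with an estimated correlation). CHAC1 went from 20.2 ± 2.22 to 73.3 ± 4.5 CPM (1.86 ± 0.15), DDIT4, an mTORC1 inhibitor, from 66.6 ± 12.5 to 198 ± 24.7 (1.57 ± 0.13) and SESN2 from 60.3 ± 10.1 to 153 ± 12.5 (1.35 ± 0.12), and DDIT3, the transcription factor CHOP, rose by 1.16 ± 0.13. None of these 4 had moved at 2 h past the threshold. SESN2 is also on the p53 target list, where 5 of 33 members rose and 0 fell (5 and 0 adjusted over the list alone), with GADD45A at 1.00 ± 0.16, BBC3, a mediator of apoptosis, at 0.67 ± 0.11 and PMAIP1 at 0.49 ± 0.10. That list had a median of 0.10 (camera adjusted p = 0.000318, adjusted p = 0.0282 with an estimated correlation). Of the 24 cholesterol genes 0 rose and 1 fell (0 and 2 adjusted over the list alone). Their median was -0.18, and the list was called with the preset correlation only (0.000304, and adjusted p = 0.249 with an estimated correlation). Of 16 chaperones 1 rose and 3 fell, the latter SDF2L1 (-0.55 ± 0.10), CALR (-0.46 ± 0.09) and PDIA4 (-0.51 ± 0.12), with 1 and 5 adjusted over the list alone. That list was not called (median -0.14, camera adjusted p = 0.0605). Epithelial markers had 5 members higher and 1 lower of 21 (7 and 2 adjusted over the list alone), among them the transcription factor ELF3 (0.95 ± 0.10). Their median was 0.16, called with the preset correlation only (0.0014, and adjusted p = 0.153 with an estimated correlation). Ribosomal proteins, with 0 members called at all, had a median of 0.14 (camera adjusted p = 0.000304, adjusted p = 0.652 with an estimated correlation).

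Genes that fell by 8 h in siControl included ESM1 (42.7 ± 7.33 to 13 ± 2.58 CPM, -1.72 ± 0.16), the purinergic receptor P2RY11 (-1.37 ± 0.26), AVIL, an actin regulator (-1.37 ± 0.31), COL27A1, a fibrillar collagen (-1.27 ± 0.21), the potassium channel KCNJ14 (-1.22 ± 0.23), the heat shock protein HSPA1A (-1.10 ± 0.13) and WNK4 (-1.80 ± 0.40). Calls for AVIL and WNK4 were kept in 3 of the 6 fits that left out 1 library, and those for the others in all 6. For WNK4 this fall and the knockdown change at 0 h rest on the same siControl 0 h samples. The total of 399 became 739 without siControl 0 h replicate 1, 189 without 0 h replicate 2, 263, 180 and 248 without 8 h replicates 1, 2 and 3, 131 in a fit to these 2 groups, and 681 with DESeq2.

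**Figure D3:**
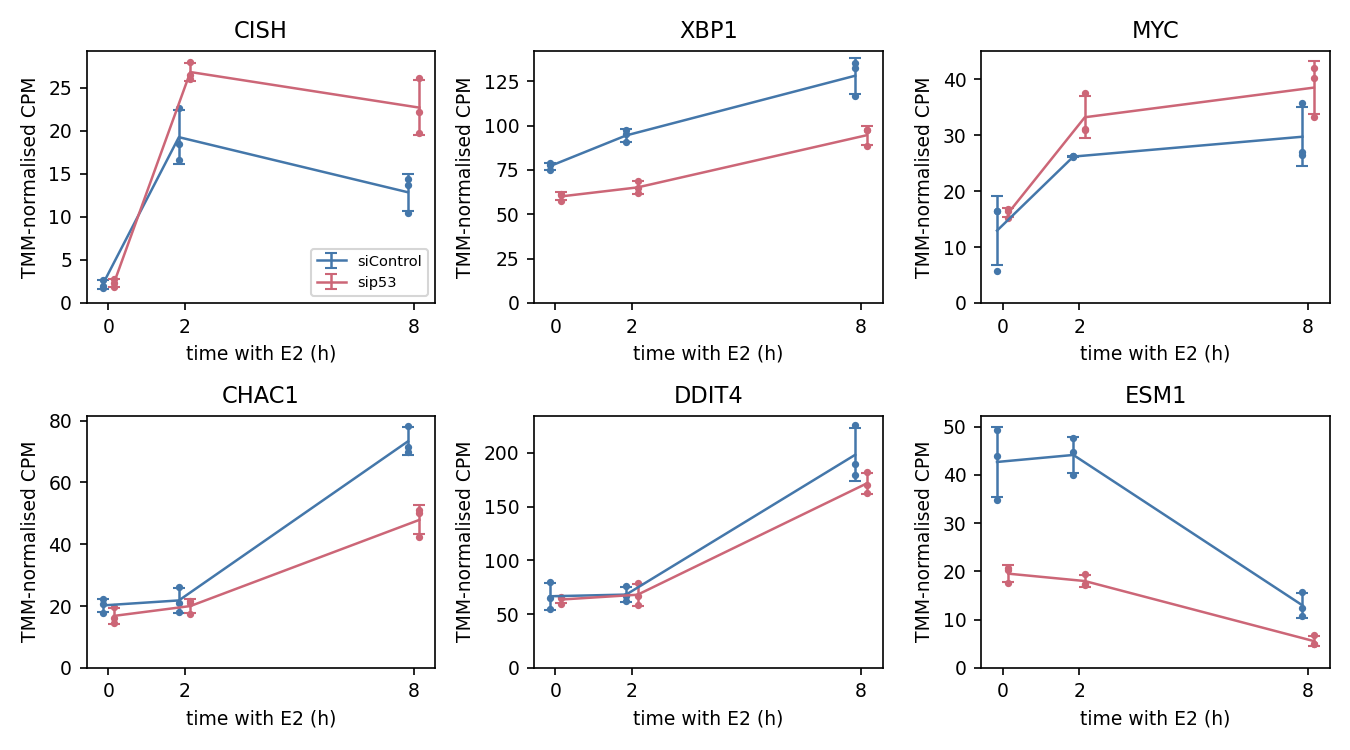
TMM-normalised CPM of 6 genes against time with E2 (h), for each library (points) with mean and SD (lines and bars, n = 3), in siControl and sip53. CISH was 2.11 and 2.32 CPM at 0 h and 19.3 and 26.8 CPM at 2 h in siControl and sip53, and ESM1 fell from 42.7 to 13 and from 19.5 to 5.54 CPM by 8 h.

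In sip53 41 genes were higher and 6 lower after 2 h of E2. CISH went from 2.32 ± 0.502 to 26.8 ± 1.03 CPM (3.53 ± 0.21), and LONRF2 (1.79 ± 0.18), the SOX factor SOX7 (1.73 ± 0.20) and RNF223 (1.70 ± 0.19) rose, as did ENST00000541740 (2.12 ± 0.25). PFKFB3, a glycolytic regulator, rose by 1.38 ± 0.17 and TFAP2C by 1.09 ± 0.09. FILIP1L fell (-1.15 ± 0.20), as did FIGN (-0.75 ± 0.15), the integrin ITGA2 (-0.55 ± 0.11) and PARD6B (-0.55 ± 0.12), the last 3 with calls kept in 2, 1 and 1 of the 6 fits that left out 1 library. Of 42 estrogen-induced genes 6 rose and 0 fell (10 and 0 adjusted over the list alone), including STC2 (0.60 ± 0.08), FHL2 (0.66 ± 0.10) and KLF4 (1.14 ± 0.18). Their median was 0.16 (camera adjusted p = 9.38e-12, adjusted p = 8.66e-05 with an estimated correlation). Camera also called the ATF4 and ribosomal protein lists (both adjusted p = 0.00476, medians 0.10 and 0.08, and adjusted p = 0.67 and 0.918 with an estimated correlation), with 0 members called in each. The total of 47 became 31 and 30 without 2 h replicates 2 and 3, and 94 with DESeq2.

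After 8 h in sip53 238 genes were higher and 181 lower. Genes that rose included CISH (3.29 ± 0.21, 22.7 ± 3.22 CPM), LONRF2 (2.01 ± 0.18), LOXL4, a lysyl oxidase (1.92 ± 0.17), RASGRP1 (1.79 ± 0.13), SLC22A3 (1.78 ± 0.18), SLC22A5 (1.77 ± 0.17) and ST6GALNAC2 (1.65 ± 0.25). Of 42 estrogen-induced genes 10 rose and 0 fell (16 and 1 adjusted over the list alone), with STC2 at 1.08 ± 0.08, KLF4 at 1.39 ± 0.18 and XBP1 at 0.65 ± 0.09. The median was 0.38 (camera adjusted p = 2.36e-15, adjusted p = 1.9e-05 with an estimated correlation). MYC rose by 1.25 ± 0.22 and CCND1, cyclin D1, by 0.40 ± 0.11. ATF4 stress genes rose here too, 6 of 20 with 0 falling (10 and 0 adjusted over the list alone), with DDIT4 at 1.43 ± 0.13, CHAC1 at 1.51 ± 0.15 and DDIT3 at 0.92 ± 0.13. Their median was 0.25 (camera adjusted p = 6.64e-18, adjusted p = 0.00219 with an estimated correlation). Of the p53 targets 2 rose, SESN2 (1.06 ± 0.12) and GADD45A (0.65 ± 0.16), and ZMAT3 fell (-0.62 ± 0.16, call kept in 0 of the 6), with 2 and 1 adjusted over the list alone, a median of 0.06 and no list call with camera (camera adjusted p = 0.234), while fry called the list higher. INSIG1, a brake on sterol synthesis, fell (-0.73 ± 0.17). The cholesterol list had a median of -0.16 and 2 lower members with either adjustment (camera adjusted p = 8.93e-05, adjusted p = 0.203 with an estimated correlation). Chaperones had 4 of 16 lower and 0 higher (6 and 1 adjusted over the list alone), including HSPA5, the BiP chaperone (-0.39 ± 0.08). Their median was -0.21 (3.18e-05, and adjusted p = 0.133 with an estimated correlation). The mitosis list had 2 lower members, AURKA (-0.43 ± 0.11) and CENPE (-0.47 ± 0.13), with 0 higher, 0 and 2 adjusted over the list alone and a median of -0.19 (8.93e-05, and adjusted p = 0.453 with an estimated correlation). The epithelial list was called with the preset correlation only, with 3 higher of 21, ELF3 (0.91 ± 0.10) among them, and a median of 0.01 (0.00709, and adjusted p = 0.203 with an estimated correlation).

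Genes that fell by 8 h in sip53 included ESM1 (19.5 ± 1.72 to 5.54 ± 1.05 CPM, -1.82 ± 0.18), FILIP1L (-1.25 ± 0.20), CCBE1, a lymphatic growth factor cofactor (-1.20 ± 0.13), P2RY11 (-1.20 ± 0.26), AVIL (-1.27 ± 0.31), the ephrin EFNB2 (-1.18 ± 0.28), FRMD4B (-1.15 ± 0.29) and PPP1R10, a phosphatase regulator (-1.11 ± 0.12). Calls for AVIL, EFNB2 and FRMD4B were kept in 2, 3 and 3 of the 6 fits that left out 1 library, and that for P2RY11 in 4. The total of 419 became 268, 271 and 255 without 0 h replicates 1, 2 and 3, 213 without 8 h replicate 3, 270 in a fit to these 2 groups, and 633 with DESeq2.

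The central comparison asked whether the knockdown altered the E2 response, and no gene passed. The difference between the arms had 0 called genes of 15318 at 2 h and 0 at 8 h (edgeR), with 451 and 583 at an unadjusted p under 0.05. DESeq2 called 1 at 2 h, CTAGE8, and 2 at 8 h, CTAGE8 among them, and limma-voom called 0 at both. Without the filter on low counts edgeR called 36 and 54. At 8 h CRTC2 (-1.17 ± 0.41), TXNIP (-1.05 ± 0.24), LOXL4 (0.80 ± 0.24) and CISH (0.71 ± 0.32) each had an adjusted p of 0.999. At 2 h PFKFB3 differed by 0.93 ± 0.24 (adjusted p = 1). Some other members of the estrogen-induced list, which holds CISH too, were closer to 0 at 8 h. They included STC2 at 0.09 ± 0.12, XBP1 at -0.08 ± 0.13, MYC at 0.07 ± 0.32 and KLF4 at 0.10 ± 0.26. The median SE of a difference was 0.272 at 8 h, and a 2-fold difference in response was recovered in 34.3% of simulated genes, so many smaller differences in single genes would be missed here. The simulated data held many changed genes, which eases the adjusted threshold, so a lone changed gene would be recovered less often.

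Over many genes the responses of the arms were close in size. At 2 h 206 genes were chosen by the average E2 effect, and 96 of them had the larger response in sip53 and 110 in siControl, with a median difference of -0.022 on the log2 scale that limma's fry did not call. At 8 h 1471 genes were chosen, with 692 larger in sip53 and 779 in siControl and a median difference of -0.018 that fry called at 0.05, against median responses of 0.49 in siControl and 0.47 in sip53. With 1 library left out the 8 h value ran from -0.127 without siControl 0 h replicate 1 to 0.038 without 0 h replicate 2. It was positive in every fit without a sip53 library and negative in most fits without a siControl library. Those fits choose genes from unequal groups, so the sign may follow the arm that lost a library. Fry no longer called the 8 h value with RLE scaling (-0.017) or upper-quartile scaling (-0.017). At 8 h 330 of the 791 genes that rose on average had the larger response in sip53, and 362 of the 680 that fell. At 2 h these counts were 57 of 135 and 39 of 71. Over all tested genes the unsigned median difference at 8 h was also -0.018, and 0.002 with upper-quartile scaling. In 50 groupings of the samples, the real one among them, a signed median difference as far from 0 came up in 42 at 2 h and 40 at 8 h. Groupings that part the arms unevenly carry the knockdown difference, so this comparison is a wide one and cannot settle whether the difference is real. Over the 42 estrogen-induced genes fixed beforehand the median difference was -0.038 at 2 h and 0.015 at 8 h, where the mean was negative (-0.019), and fry called neither. The responses of the 2 arms correlated across the chosen genes with r = 0.73 at 2 h and 0.78 at 8 h. Genes are not independent replicates, and the choice by the average of both arms favours genes that move the same way in both. Called in both arms were 21 genes higher at 2 h (0.1 expected if the calls were independent), 125 higher at 8 h (4.2 expected) and 52 lower at 8 h (1.5 expected). The arms were tested against their own 0 h samples, but in the same fit with a shared estimate of spread, so these calls are not fully independent either.

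**Figure D4:**
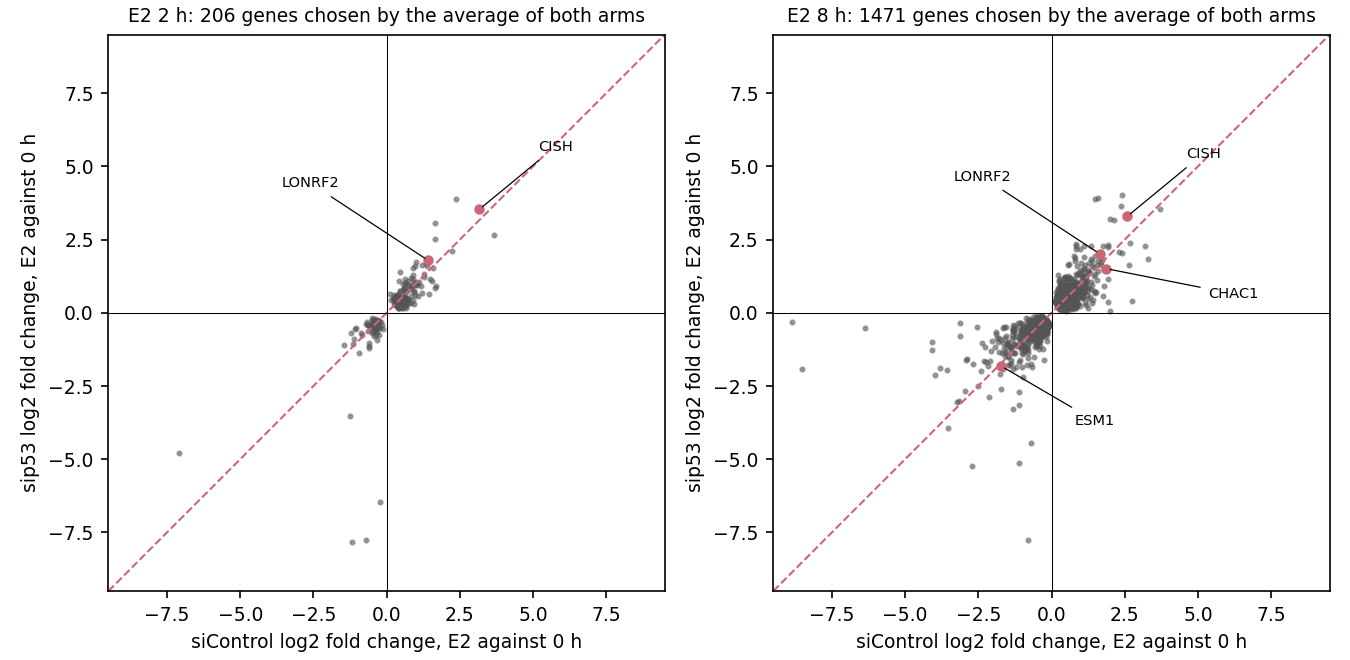
Log2 fold change of E2 against 0 h in sip53 (vertical axis) and in siControl (horizontal axis) for 206 genes at 2 h (left) and 1471 genes at 8 h (right), chosen by the average E2 effect over both arms, with the line of equal response dashed. Of these genes 96 and 692 had the larger response in sip53.

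With camera, gene lists differed between the arms only with the preset correlation. At 2 h 1 list was called, unfolded protein response chaperones, with a median difference of -0.213. At 8 h 6 lists were called, each with a negative median difference. They were ATF4 stress genes (median -0.178), p53 targets (-0.166), estrogen-repressed genes (-0.215), mitosis (-0.135), ribosomal proteins (-0.105) and chaperones (-0.12). None was called with an estimated correlation (lowest adjusted p = 0.381 at 8 h with an estimated correlation), and 0 of their members were called over all genes. At 8 h fry called p53 targets and estrogen-repressed genes at 0.05, not adjusted over lists.

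The last comparison set 8 h against 2 h within each arm, to separate early from late changes. In siControl 99 genes were higher and 58 lower at 8 h, and in sip53 126 were higher and 85 lower. Of 20 ATF4 stress genes 6 in siControl were higher at 8 h than at 2 h and 0 lower (12 and 0 adjusted over the list alone, median 0.375, camera adjusted p = 3.84e-31, adjusted p = 0.000275 with an estimated correlation), with CHAC1 at 1.75 ± 0.15 and DDIT4 at 1.54 ± 0.13. In sip53 5 were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 5.53e-11, adjusted p = 0.0332 with an estimated correlation), with DDIT4 at 1.33 ± 0.13 and CHAC1 at 1.26 ± 0.15. Chaperones were lower at 8 h than at 2 h, 5 of 16 in siControl and 3 in sip53 with 0 higher (10 lower and 1 higher, and 4 and 0, adjusted over the list alone). Their medians were -0.31 and -0.19 (camera adjusted p = 7.29e-11 and 8.25e-06, adjusted p = 0.0167 and 0.0671 with an estimated correlation), with SDF2L1 at -0.64 ± 0.10 and -0.53 ± 0.09. STC2 and XBP1 went on rising in both arms, STC2 by 0.63 ± 0.08 and 0.48 ± 0.08 and XBP1 by 0.44 ± 0.09 (call kept in 2 of the 6 fits that left out 1 library) and 0.54 ± 0.09. ESM1 fell after 2 h in both (-1.77 ± 0.16 and -1.70 ± 0.18). SOX7, an early riser, came down again in both (-1.23 ± 0.20 and -1.07 ± 0.19), and in sip53 so did PFKFB3 (-1.10 ± 0.17), CCN2 (-1.15 ± 0.18) and CCN1 (-1.06 ± 0.17). The cholesterol list had medians of -0.18 and -0.18 (camera adjusted p = 6.06e-09 and 1.66e-05, adjusted p = 0.0679 and 0.127 with an estimated correlation). The host gene of a microRNA, MIR503HG, rose in both (1.80 ± 0.26 and 1.60 ± 0.25). The totals of 157 and 211 became 350 and 406 with DESeq2, and 211 became 375 in a fit to the 2 groups. Left out in turn, siControl 2 h replicates 2 and 3 gave 88 and 81, and 8 h replicates 1, 2 and 3 gave 90, 87 and 103. In sip53, 2 h replicates 1, 2 and 3 gave 117, 105 and 120, and 8 h replicate 1 gave 135.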

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

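The tests of reads shared between copies, of a single library behind the cholesterol result and of the carriers of the seed word in the gene lists were chosen only after the results were seen.

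A difference between the arms in the E2 response marked the following results. Unfolded protein response chaperones differed at 2 h with a median of -0.213 (camera adjusted p = 8.25e-05, adjusted p = 0.382 with an estimated correlation). At 8 h the medians were -0.215 for estrogen-repressed genes (0.0313, and adjusted p = 0.381 with an estimated correlation), -0.166 for p53 targets (0.0362, and 0.381), -0.135 for mitosis (0.0124, and 0.766), -0.105 for ribosomal proteins (0.0124, and 0.801), -0.12 for chaperones (0.0428, and 0.655) and -0.178 for ATF4 stress genes (0.0169, and 0.537), the later values being those with an estimated correlation. The size of the E2 response at 8 h differed by -0.018, which fry called at 0.05.

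These differences were compared with other groupings of the samples. At 2 h 50 groupings of a possible 200 were used, the real one among them. Every one had at least the 0 called genes of the real one (highest 1234), which a count of 0 makes certain. Of the 50, 42 had at least 1 called list (highest 7) and 42 had a response size as far from 0 as the real -0.022 (highest 0.236). At 8 h the numbers were 50 of 50 (highest 393) for called genes, again certain with 0, 9 of 50 with at least 6 lists (highest 8) and 40 of 50 as far from 0 as -0.018 (highest 0.19). Groupings that part the arms unevenly carry the knockdown difference, which may explain the large counts among them, so this comparison is a wide one. The counts of called genes decide nothing here. Within it the list calls and the size difference may be no more than the grouping of 3 samples would give.

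For the contrasts of 2 groups, 10 groupings exist, too few for a share under 0.05. The real grouping alone had the largest count of genes each time, with 1397 against at most 58 in any other for the knockdown at 0 h, 1871 against 0 at 2 h and 1372 against 0 at 8 h. For E2 the counts were 35 against 0 (2 h, siControl), 399 against 0 (8 h, siControl), 47 against 0 (2 h, sip53) and 419 against 1 (8 h, sip53), and for 8 h against 2 h they were 157 against 1 (siControl) and 211 against 0 (sip53). In each of these 9 comparisons 1 grouping of the 10, the real one, reached its own count. In a mixed grouping a difference between the real groups widens the spread within groups, which can lower its count. The low counts of the other groupings are therefore weak evidence. List calls separated less well. For the knockdown 7 lists at 0 h were reached by 3 of 10 groupings (highest other 8), 9 at 2 h by 1 (highest other 7) and 8 at 8 h by 1 (highest other 4). For E2 at 2 h 5 lists in siControl were reached by 5 (highest other 9) and 3 in sip53 by 4 (highest other 6), and at 8 h 7 in siControl by 1 (highest other 6) and 6 in sip53 by 1 (highest other 4). For 8 h against 2 h 9 lists in siControl were reached by 2 (highest other 9) and 10 in sip53 by 1 (highest other 4).

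The first pattern weighed was the set of 416 genes lower in sip53 at all 3 times. An off-target seed effect of the siRNA predicts a 7-base word enriched in the 3' UTRs of lowered genes, and 2 words passed at all 3 times out of 16181 (threshold |t| = 4.66), GTGGAGT and AAAAAAA, with 0 on the higher side. GTGGAGT had t = -5.29, -6.72 and -6.01 at 0, 2 and 8 h and lay in 20.2% of the searched lower genes (75 of 371) against 4.6% of the higher and 9.6% of the other genes. AAAAAAA had t = -7.28, -5.61 and -4.88, and -3.46 and -4.26 for E2 at 2 h and 8 h in siControl, where the siRNA does not differ, so passing this search does not by itself point to a seed. For E2 at 2 h and 8 h GTGGAGT had t = 0.01 and -0.08 in siControl, and -1.6 and -0.96 in sip53. In the E2 contrasts 0 words passed on the lower side, and 1 passed on the higher side, at 2 h in siControl. The siRNA sequence is not in the sources used, so a seed effect is a candidate explanation for some of the lower genes. The excess of carriers was 39.4 genes, not corrected for the longer 3' UTRs of this set, and the other lower genes were left open. Carriers of the word include RPS27L, ACLY and SLC7A11.

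A trend between libraries with transcript length or GC content was also weighed for these 416 genes. The 3' UTRs of the 371 that were searched had a median of 1785 nt and 35.8% GC against 1138 nt and 42.3% in other genes. With the trend removed 66.8% of the 416 (278) stayed lower at all 3 times, and the medians of the whole set went from -0.65, -0.75 and -0.68 to -0.56, -0.6 and -0.56. The trend could account for some of the calls and this test does not decide how many. Without the carriers of GTGGAGT the p53 target list kept medians of -0.24, -0.2 and -0.31 at 0, 2 and 8 h, so the word does not account for its direction.

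The second pattern was the rise of cholesterol synthesis genes. With the trend removed the lowest of the 3 medians was 0.312, and over the fits that left out 1 library it was 0.367, so neither a length or GC trend nor any single library explains the whole of it. Loss of p53 activity, lower sterol supply, or another effect of the reagent were not told apart.

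The third pattern was the fall of NPIP family members at 0 h, where reads can move between copies. The counts summed over 24 members fell by 0.97 on the log2 scale at 0 h (adjusted p = 0.00531), with 9 members lower and 0 higher, so movement of reads among these copies alone does not explain it. At 2 h the sum stood at -0.82 (adjusted p = 0.0096), with 9 members lower and 0 higher. At 8 h it stood at -0.32 (adjusted p = 0.33), with 3 members lower and 1 higher and the lowest member at -9.89. Movement of reads among copies was left open at 8 h.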

How the results depend on the processing

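Of the 458 calls of named genes, 455 were kept with RLE scaling, 449 with upper-quartile scaling, 443 without the low-count filter, 456 with the CPM filter, 442 with the replicate block, 451 of 457 with DESeq2, 443 with limma-voom and 361 of 456 in fits to the groups of the contrast. Over the fits that left out 1 library 2076 of 2748 were kept, and 252 of the 458 were kept in every one. None reversed. The causes of the changes below were not tested, except that fits with fewer samples have less power by construction and a stricter threshold gives fewer calls. Depth of 7542457 to 11307199 counts limits genes of a few CPM, such as GREB1.

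With no filter (26224 genes tested) the counts of changed genes were 285 and 789 for E2 at 2 h and 8 h in siControl, 204 and 701 in sip53, 313 and 403 for 8 h against 2 h in siControl and sip53, and 36 and 54 for the difference between arms at 2 h and 8 h. Of the last, 36 and 52 lay among the 15318 genes, and the prior degrees of freedom went from 10.6 to infinite without the filter. With a 2-fold threshold the counts were 216, 317 and 194 for the knockdown at 0, 2 and 8 h, 12 and 113 for E2 in siControl, 24 and 95 in sip53, and 31 and 61 for 8 h against 2 h. DESeq2 gave 130 and 681 for E2 in siControl, 94 and 633 in sip53, 350 and 406 for 8 h against 2 h, and 1 and 2 for the difference between arms. Fits to the groups of the contrast gave 284 for the knockdown at 0 h, 13 and 131 for E2 in siControl, 270 for E2 at 8 h in sip53 and 375 for 8 h against 2 h in sip53. The replicate block gave 1448, 1868, 1419, 28, 372, 43, 430, 150, 205, 0 and 0 for the 11 contrasts in the order of the methods.

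Leaving out 1 library gave 289 to 2043 changed genes for the knockdown at 0 h, 821 to 1923 at 2 h and 399 to 1466 at 8 h. For E2 it gave 17 to 144 and 180 to 739 at 2 h and 8 h in siControl, and 30 to 42 and 213 to 343 in sip53. For 8 h against 2 h it gave 81 to 105 and 105 to 154, and for the difference between arms 0 to 0 at both times. The median difference in response size ran from -0.206 to 0.072 at 2 h and from -0.127 to 0.038 at 8 h. At both times it was positive in every fit without a sip53 library and negative in most fits without a siControl library. Those fits choose genes from unequal groups, so these signs may follow the arm that lost a library. They do not settle whether the direction is stable. The 8 h size, called by fry in the fit as reported, was not called with RLE scaling (-0.017), upper-quartile scaling (-0.017), no filter (-0.028), fits to the groups (0.002) or the fixed estrogen list (0.015), and the 2 h size with fits to the groups was 0.03. With an estimated correlation in camera, 2 list calls of the knockdown at 2 h were lost. They were p53 targets (median -0.159, adjusted p = 0.116) and cholesterol genes (median 0.379, adjusted p = 0.0642).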

Other observations

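Interferon genes leaned lower in sip53, with 0 of 31 higher and 2, 4 and 3 lower at 0, 2 and 8 h (0 and 2, 0 and 6, and 0 and 3 adjusted over the list alone). RIGI, an RNA sensor, stood at -0.67 ± 0.14, -0.71 ± 0.14 and -0.55 ± 0.14, and IFIT2 at -0.66 ± 0.17 and -0.79 ± 0.17 at 2 h and 8 h. The list medians were -0.243, -0.341 and -0.201 (camera adjusted p = 0.036, 0.0293 and 0.0568, adjusted p = 0.233, 0.288 and 0.371 with an estimated correlation). With the length and GC trend removed the 0 h and 2 h medians were -0.276 and -0.26, and the altered camera test called neither (adjusted p = 0.12 and 0.152). LTB, a lymphotoxin on the NF-kB list, was higher at all 3 times (0.81 ± 0.15, 1.00 ± 0.15 and 0.93 ± 0.15), while that list of 18 held 2, 2 and 1 higher and 1, 0 and 0 lower members and was not called (camera adjusted p = 0.0794, 0.104 and 0.16). After 8 h of E2 RSAD2, an antiviral gene, was lower than at 0 h in both arms (-0.61 ± 0.15 in siControl and -0.85 ± 0.15 in sip53), as was RELB, an NF-kB subunit (-0.52 ± 0.13 and -0.66 ± 0.13). Of 26 immediate-early genes 0 were higher and 6 lower in sip53 at 8 h, among them JUN (-0.54 ± 0.11) and ETV5 (-0.72 ± 0.16), without a list call (0 and 7 adjusted over the list alone, median -0.089, camera adjusted p = 0.131). With the length and GC trend removed the altered camera test called that list at 2 h and 8 h with the preset correlation only (medians -0.233 and -0.168, adjusted p = 0.0366 and 0.00299, and adjusted p = 0.369 and 0.2 with an estimated correlation). At 0 h 1 was higher and 3 lower, including FOSL1 (-0.67 ± 0.14), and at 2 h 2 and 2 (camera adjusted p = 0.812 and 0.7).

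Hypoxia and glycolysis genes split, with LDHA, lactate dehydrogenase, higher in sip53 at all 3 times (0.52 ± 0.08, 0.47 ± 0.08 and 0.56 ± 0.08) and VEGFA, the angiogenic factor, lower (-0.61 ± 0.17, -0.87 ± 0.17 and -0.51 ± 0.16). Of 20 genes 4, 7 and 2 were higher and 1, 1 and 2 lower at 0, 2 and 8 h, with no list call (camera adjusted p = 0.0778, 0.175 and 0.352). VEGFA rose with E2 at 8 h in both arms (0.88 ± 0.16 and 0.98 ± 0.17). Of 22 mesenchymal and matrix genes 3 were higher at 0 h, including COL4A1 (0.57 ± 0.11) and SPARC (0.49 ± 0.10), and 1 was lower, and the counts were 0 and 4 at 2 h and 0 and 2 at 8 h (camera adjusted p = 0.679, 0.7 and 0.93). Of 28 ribosome biogenesis genes 0, 0 and 1 were higher and 1, 5 and 0 lower, with NOP56 at -0.87 ± 0.20 at 2 h (camera adjusted p = 0.997, 0.672 and 0.467). Between 2 h and 8 h the small nuclear RNA RNU4-1 rose by 2.19 ± 0.27 in sip53 and was not called in siControl (0.92 ± 0.26, adjusted p = 0.101), and 7SK rose by 0.94 ± 0.20 in siControl and 1.69 ± 0.20 in sip53. As RNAs mostly without a poly(A) tail they are uncertain in 3' end data. Fibroblast markers had 3 measured members with FAP lower at 2 h (-0.87 ± 0.20) and no list call (camera adjusted p = 0.764, 0.665 and 0.652). Leukocyte and endothelial markers had 2 measured members each and 0 called by edgeR in the knockdown, and mitochondrially encoded genes had 0 measured.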
